A study of Caenorhabditis elegans with 2 samples.

How the data were processed

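Peak lists from 2 ChIP-seq libraries of whole young adult C. elegans (63.5 h, grown from starved L1 larvae) were used. Both came from a strain with B0019.2 tagged by genome editing and were precipitated with an antibody against GFP after sonication to 200 to 800 bp, per the labels. Both libraries are biological replicates per the labels and form 1 group. Coordinates are on assembly ce11, per the labels and the readme files. The aligner, the peak caller and their versions are not given in the sources used here.

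The authors deposited, for each library and for both libraries together, a ranked list of candidate peaks and a thresholded list. Lists of both libraries were made by the authors from both alignments, and 1 thresholded list among them is named conservative. That thresholded list was the main list. IDR, the irreproducible discovery rate, scores how well the ranks of peaks agree between inputs. In the deposited lists the signal value of a peak is a non-negative signal given by the authors, with no stated scale. The deposited score of each peak was not used in any test. The deposited ranked lists also give −log10 of the global IDR. Every thresholded peak was found in its ranked list with −log10 global IDR of at least 2, that is an IDR of at most 0.01. For the lists of both libraries this held by choice, since the ranked list was picked as the one that met it. The thresholded lists lacked 88 regions that reached this value in the main ranked list, 90 in the other, 57 in that of replicate 1 and 72 in that of replicate 2. The readme files name a further, undescribed input for the thresholded lists. The ranked lists of both libraries hold 16 columns of values per input that no label ties to a sample, and these were not used.

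The lists hold no counts, so depth per library is unknown, and no statement here rests on it. Signal values were used to describe, rank and split peaks within a list, never between lists. Intervals on shares are exact 95% binomial intervals and cover counting error only, and neighbouring genes that share a peak are not independent.

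Genes came from the Ensembl release 115 annotation of WBcel235, which has the chromosome coordinates of ce11, on 6 nuclear chromosomes. Gene lists and motifs were fixed before the data were examined. A summit was assigned to every gene whose window (1000 bp upstream to 200 bp downstream of the gene start) held it. Classes were taken in the order promoter, 5′ UTR, 3′ UTR, coding exon, non-coding exon, intron and intergenic. Promoter and chromosome shares were set against the remaining peaks of the ranked list, which include the 88 regions. Gene classes and gene lists were set against other genes with a ranked candidate in the window. The tests were Fisher's exact tests (two-sided) at 0.05. Benjamini-Hochberg adjustment was applied over gene classes, gene lists, motifs and 6-mers. It was not applied to promoter, chromosome or divergent gene shares.

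Replicate peaks were matched where the overlap was at least 50% of either peak, and chance levels came from 1000 draws. Motifs and 6-mers were counted as present or absent within 50 bp of the summit and in windows centred 300 bp to either side. An exact sign test compared peaks with a match only at the summit and only in a flank, with both counts averaged over the flanks and rounded.

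The 25 strongest main peaks found in both libraries' thresholded lists were taken. Named genes were B0019.2, the nearest gene to each of the 21 of these summits that lay in a window, and up to 4 members of each gene list by signal value. Genes of the 4 summits outside windows were named after their values were seen. On simulated data, 50 random draws of 900 candidates gave 0 calls over 23 lists among 10361 genes. A list of 60 genes given 24 added peaks was recovered in 50 of 50 draws. For 6-mers, 20 draws of 900 candidates with windows in random order gave 0 calls among 2080, and a 6-mer placed in 90 summit windows was recovered in 20 of 20. The draws came from all candidates, which lay at promoters less often than the main peaks. Windows in random order carry no GC difference between summit and flank. These simulations therefore do not show the error rate of the tests on the main peaks. Nor do they show how often a list with fewer bound members, such as the 6 of 31 proteasome genes, would be found.

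Alternatives were the other deposited list, the upper part of the main list by signal value (450 peaks), each library's own list, other windows (500 and 100 bp, 2000 and 500 bp), backgrounds, gene starts, assignments, overlap rules and sequence windows. Control libraries were not analysed here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.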

Results

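The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the Caenorhabditis elegans protein B0019.2, annotated as containing an SPK domain. Whole young adult worms aged 63.5 h carried a genome-edited B0019.2 gene whose product was fused to a TY1 epitope, EGFP and a triple FLAG tag, and chromatin was precipitated with an antibody against GFP. There was 1 group of 2 biological replicates, and control libraries were not analysed here. The comparisons were therefore made between the replicates, and between peaks that passed the authors' reproducibility threshold and the candidate peaks that did not. The lists hold no read counts, so the sequencing depth behind each peak is unknown. The authors' signal value of a peak was used to describe, rank and split peaks within a list.

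The main list held 900 peaks that covered 231 kb, or 0.231% of the 6 nuclear chromosomes, and was taken from 55591 ranked candidates. The median signal value was 95.7 in this list, with quartiles of 77.2 and 131. The lists of the single libraries held 524 peaks in replicate 1 and 496 in replicate 2. The other deposited list made from both libraries held 866 peaks.

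The peak with the highest signal value, 697, lay on chromosome I at 3931803 to 3932042 (assembly ce11). Its summit was 288 bp upstream of the start of egg-4, which encodes a regulator of the oocyte-to-embryo transition, and the peak ranked first in both replicates. The peak of the related gene egg-5, on chromosome I at 4171749 to 4171949, had a signal value of 307 and a summit 264 bp upstream. This summit also lay in the window of the spliced leader RNA gene sls-2.4. The summit 228 bp upstream of cpg-1, a proteoglycan of the eggshell, had a signal value of 342. Among the 25 strongest peaks found in the lists of both libraries, 21 had their summit in a promoter window, defined as 1000 bp upstream to 200 bp downstream of a gene start. The nearest gene start was that of a protein-coding gene for 16 of them and of a non-coding RNA gene or pseudogene for 5.

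The ribosomal protein genes rpl-15, rpl-3, rps-24 and rpl-35 had peaks with signal values of 565, 547, 385 and 381. The peak of rpl-15 lay on chromosome IV at 654835 to 655026. Its summit also lay in the windows of K11H12.8 and of the snoRNA genes K11H12.13 and K11H12.12. The peak of rpl-3 lay on chromosome III at 3867479 to 3867680. The window of mog-4, a helicase gene with a role in germline sex determination, held a peak of signal value 558 on chromosome II at 14561746 to 14561949. The summit near hcp-3, the centromeric histone H3 variant, lay 640 bp upstream and had a signal value of 414. The gene for replication protein A subunit rpa-2 shared a summit with the long non-coding RNA gene M04F3.7, at a signal value of 404. Other genes named by the rule were sco-1 (388), kin-35 (361), cdc-48.1 (358), tasp-1 (334), cnk-1 (332), the histone chaperone gene unc-85 (320) and ubc-6 (305), each with the signal value of its peak. The summit of ubc-6 also lay in the window of aka-1, and that of tasp-1 in the window of K01G5.10. That of cdc-48.1 also lay in the window of the snoRNA gene C06A1.9. The summits of kin-35 and rps-24 each also lay in the window of a pseudogene.

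Non-coding genes were nearest to 5 of these summits. They were the ncRNA genes C10G11.12 (signal value 572) and C46C2.12 (546), the lincRNA gene M04F3.7, a pseudogene on chromosome IV with the identifier WBGene00023323 (524), and the piRNA gene 21ur-963 (495). The summit nearest 21ur-963 also lay in the windows of the piRNA genes 21ur-13458, 21ur-13102, 21ur-10800, 21ur-16, 21ur-10334 and 21ur-9674. The other 4 strong peaks lay outside promoter windows. Of these, 3 were in introns, of T06D8.10 (523), nstp-10 (378) and let-363 (364), the last being the worm TOR kinase. The other was intergenic, on chromosome I at 316185 to 316332 (316). No peak of the main list, or of either library's list, had its summit in B0019.2 itself or within 1000 bp upstream of it (chromosome I, 12773659 to 12782257, plus strand). The gene held 4 ranked candidates, of which the strongest had a signal value of 56.7 and did not reach the threshold.

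The replicates shared most of their strongest peaks. Of the 524 peaks of replicate 1, 340 (64.9%, exact 95% interval 60.6 to 69.0) overlapped a peak of replicate 2 by at least 50% of either peak. Of the 496 peaks of replicate 2, 340 (68.5%, 64.3 to 72.6) overlapped a peak of replicate 1. Draws of as many peaks from the same library's candidates gave means of 1.06% and 1.30% (one-sided permutation p = 0.001 in both directions, the smallest that 1000 draws can give). Random placement on the same chromosome gave 0.157% and 0.169% (one-sided permutation p = 0.001). Of the 131 peaks of replicate 1 with the highest signal values, 98.5% were found in replicate 2, against 26% of the 131 with the lowest (Fisher's exact test, two-sided, p = 3.65e-39). For the 124 highest and 124 lowest peaks of replicate 2 the shares were 99.2% and 38.7% (Fisher's exact test, two-sided, p = 5.56e-29). Of the 900 main peaks, 465 (51.7%) were in the list of replicate 1, 442 (49.1%) in that of replicate 2, 336 (37.3%) in both and 329 (36.6%) in neither.

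**Figure D1:**
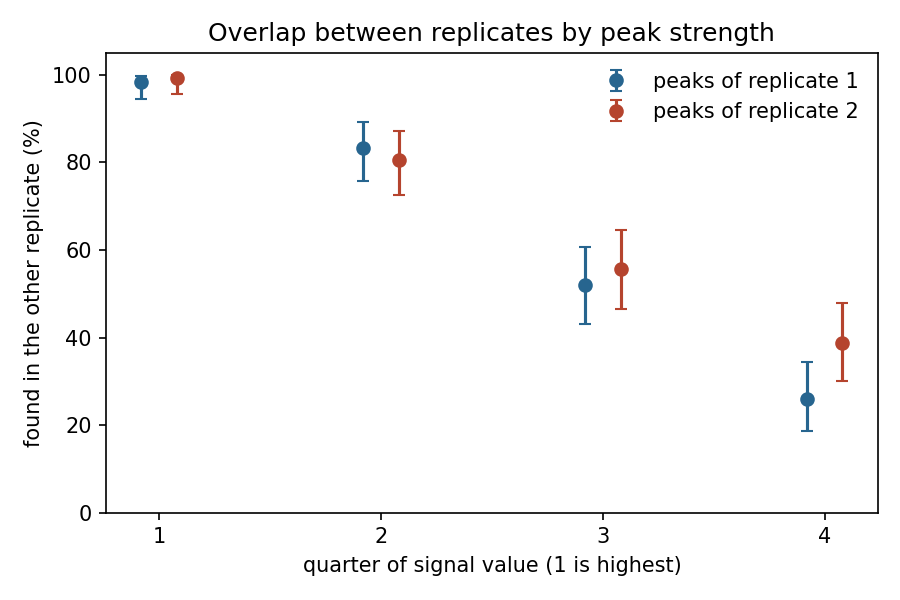
Share of each replicate's peaks found in the other replicate (y axis, %) by signal value within its own list (x axis, 4 classes of equal size, 1 is the highest), with exact 95% binomial intervals. The share falls from 98.5% to 26% for replicate 1 and from 99.2% to 38.7% for replicate 2.

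Peaks lay mostly at promoters. The summits of 726 of 900 peaks (80.7%) were in a promoter window, against 18881 of 54691 remaining candidates (34.5%), an odds ratio of 7.91 (95% interval 6.69 to 9.40, Fisher's exact test, two-sided, p = 1.42e-174). Random genome positions lay in a promoter window in 34.6% of cases (odds ratio 7.87). The remaining candidates thus lay at promoters no more often than random positions. With the window of 2000 and 500 bp the odds ratio was 5.24. Introns held 59 summits (6.56% against 23.5% of candidates), intergenic sequence 70 (7.78% against 13.7%) and coding exons 20 (2.22% against 23.6%). Most of the window is upstream by definition. Relative to the nearest gene start of any class, the median of the 726 promoter summits lay 121 bp upstream and 79.3% were upstream. Relative to the nearest protein-coding gene start, the median of 548 summits lay 218 bp upstream and 92.9% were upstream. Of the 726 promoter peaks, 397 had their summit in the windows of more than 1 gene.

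**Figure D2:**
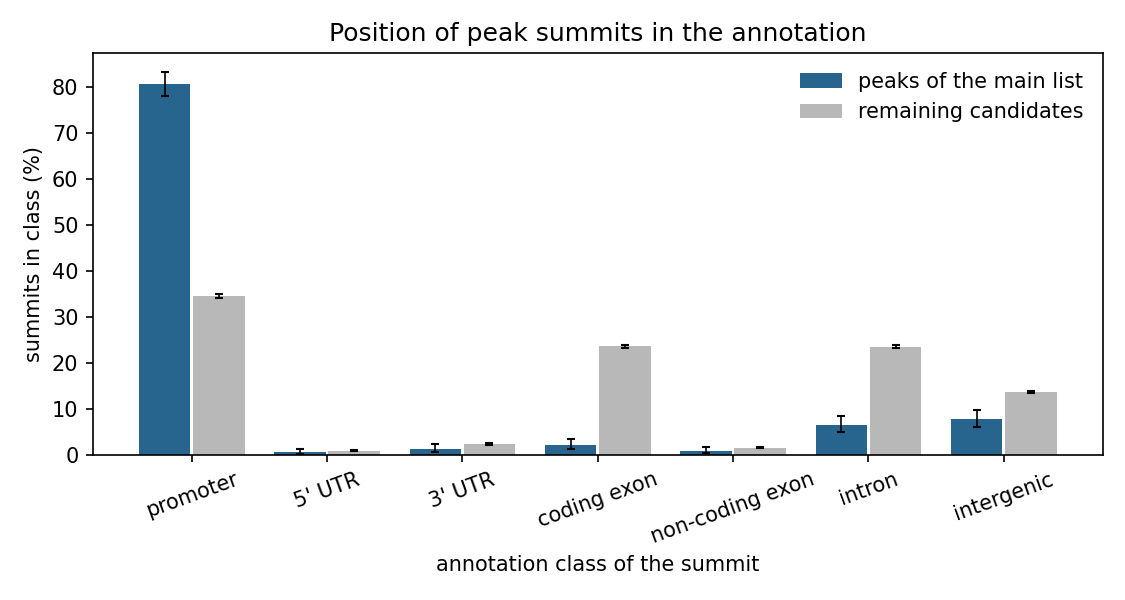
Annotation class of peak summits (x axis) as a share of all summits (y axis, %), for the 900 main peaks and the 54691 remaining candidates, with exact 95% binomial intervals. Promoters hold 80.7% of the peaks and 34.5% of the candidates.

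Genes with a summit in the promoter window often had a divergent neighbour. Such genes are called bound below, whether or not the window of another gene also held the summit. The word does not mean that binding was tested against control libraries. Of the 766 protein-coding genes with a summit in the window, 379 (49.5%) had a protein-coding gene start on the opposite strand, pointing away, within 1000 bp. The share was 19.7% of 9595 other protein-coding genes with a candidate (odds ratio 4.0, 95% interval 3.43 to 4.66, Fisher's exact test, two-sided, p = 2.86e-69). A summit between divergent genes lies in both windows, and with each summit given only to its nearest gene start the odds ratio was 2.26.

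The X chromosome held few peaks. It carried 55 of 900 summits (6.11%) against 16.4% of the remaining candidates (odds ratio 0.332, 95% interval 0.247 to 0.436, Fisher's exact test, two-sided, p = 2.71e-20). Of these 55, 35 lay in the window of a tRNA gene. Without tRNA gene summits the odds ratio was 0.132, an alternative chosen after seeing the data. It was 0.206 without replicate 2 and 0.176 in the upper part of the list by signal value. Chromosomes I, III and IV held more summits than candidates in proportion (22.1% against 16.2%, 21.1% against 15.3% and 19.8% against 15.6%), and chromosome V held fewer (13.4% against 20.3%). Fisher's exact test (two-sided) gave unadjusted p = 5.03e-06, 4.67e-06, 0.000854 and 1.22e-07 for these 4 chromosomes and p = 0.316 for chromosome II. Chromosome IV did not pass against random positions (17.5%, odds ratio 1.16, Fisher's exact test, p = 0.0783) or without replicate 1 (1.24, p = 0.0643). The central 50% of the length of each autosome held 59.3% of autosomal summits and 49.8% of candidates (Fisher's exact test, two-sided, p = 3.83e-08).

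**Figure D3:**
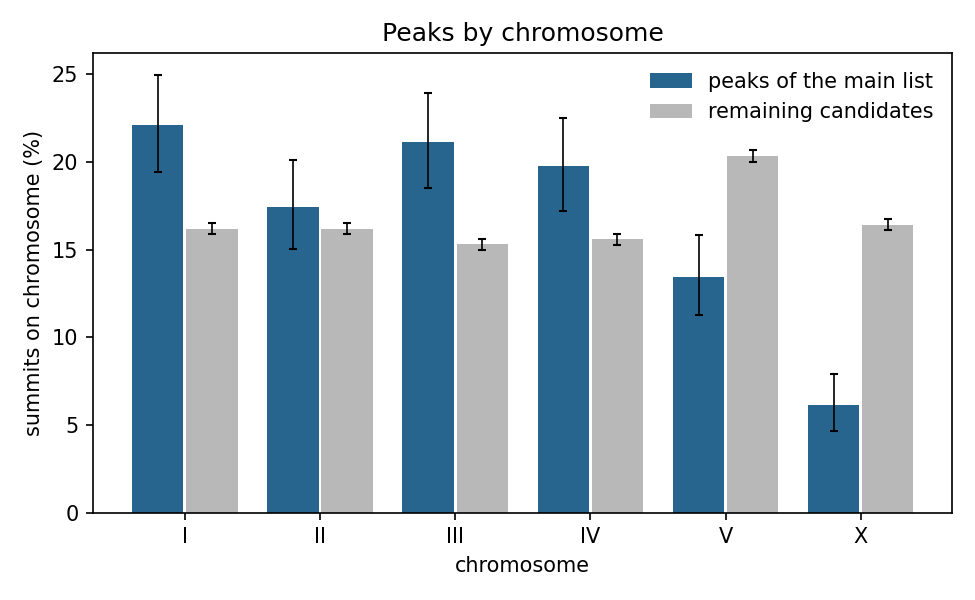
Share of summits on each chromosome (y axis, %; x axis, chromosome) for the 900 main peaks and the 54691 remaining candidates, with exact 95% binomial intervals. The X chromosome holds 6.11% of the peaks and 16.4% of the candidates.

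Genes for tRNA, snoRNA and snRNA held peaks more often than other genes. A main summit was in the window of 115 of 523 tRNA genes with a candidate (22%, odds ratio 4.37), 69 of 260 snoRNA genes (26.5%, 5.46) and 22 of 83 snRNA genes (26.5%, 5.28). Protein-coding genes held one in 766 of 10361 cases (7.39%, odds ratio 1.38). Shares were lower than in other genes for piRNA genes (70 of 3213, odds ratio 0.283), other non-coding RNA genes (203 of 4410, 0.641) and pseudogenes (33 of 907, 0.534). Benjamini-Hochberg adjusted p over 8 gene classes (Fisher's exact test, two-sided) was 1.50e-31 for tRNA, 3.29e-24 for snoRNA, 1.42e-08 for snRNA, 4.71e-08 for protein-coding, 9.74e-33 for piRNA, 6.86e-09 for other non-coding RNA and 0.000206 for pseudogenes. The miRNA genes did not pass (11 of 150, odds ratio 1.14, Fisher's exact test, adjusted p = 0.617). These tests count genes, and genes that share a summit, such as neighbouring piRNA genes, are not independent, so the p-values are too small where summits are shared. The tRNA odds ratio was 2.18 without replicate 1, 2.35 without replicate 2 and 1.64 in the upper part of the list by signal value (Fisher's exact test, adjusted p = 4.41e-05, 2.67e-06 and 0.0175). Under the same 3 settings the odds ratio was 2.09, 2.07 and 2.24 for protein-coding genes and 0.134, 0.159 and 0.171 for piRNA genes, for which it was lowest with nearest gene starts (0.108). The snRNA odds ratio was 3.51 without replicate 2 and 9.42 with nearest gene starts, where that of snoRNA was 6.16. Some summits in snoRNA windows, such as those of rpl-15 and cdc-48.1, also lay in protein-coding windows. Such shared summits were not set apart for snoRNA or snRNA genes. Against all annotated genes the odds ratio was 8.89 for tRNA and 9.25 for snoRNA genes. The miRNA genes passed without replicate 2 (2.05, Fisher's exact test, adjusted p = 0.0292). Against all annotated genes, the odds ratio of other non-coding RNA genes was 0.898 and no longer passed (Fisher's exact test, adjusted p = 0.178).

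Of 23 gene lists fixed before the data were examined, 10 held peaks more often and 2 less often than other protein-coding genes with a candidate. Genes for oogenesis and maternal RNA regulation were bound in 27 of 52 cases (odds ratio 14, 95% interval 7.76 to 25.25). After egg-4 and egg-5, the strongest were the RNA-binding protein genes larp-1 (signal value 204) and mex-1 (200). Ribosomal protein genes were bound in 36 of 73 cases (odds ratio 12.7, 7.77 to 20.9). For cell cycle and DNA replication genes the share was 27 of 72 (odds ratio 7.75, 4.60 to 12.8), led by hcp-3, the centromere protein gene hcp-4 (303), the replicative helicase subunit gene mcm-2 (230) and the kinetochore gene hcp-1 (196). Benjamini-Hochberg adjusted p over the 23 lists (Fisher's exact test, two-sided) was 1.72e-16, 1.25e-20 and 2.71e-12 for these lists. With each summit given only to its nearest gene start, the odds ratio of ribosomal protein genes was 6.45. Of bound genes, 16 of 36 ribosomal protein, 20 of 27 oogenesis and 18 of 27 cell cycle genes were the nearest gene start to their strongest summit. The gene larp-1 was not. Against all annotated protein-coding genes the odds ratios of the 10 lists were 5.30 to 20.99.

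P granule and small RNA pathway genes were bound in 13 of 55 cases (odds ratio 3.93), with nrde-2 (signal value 251), glh-2 (178), pid-5 (153) and hrde-1 (150) the strongest. Meiosis genes were bound in 10 of 44 cases (3.72), led by the cohesin gene rec-8 (155). Next were syp-6 and mei-2, which shared 1 summit (154), and coh-4 (153), which shared its summit with pid-5 of the P granule list. Chromatin regulators were bound in 17 of 73 cases (3.87), with unc-85, set-16 (240), the histone variant gene htz-1 (219) and isw-1 (193) the strongest. Adjusted p (Fisher's exact test, two-sided) was 0.000462, 0.00326 and 9.79e-05 for these lists. In the same order, 8 of 13, 6 of 10 and 9 of 17 bound genes were the nearest gene start to their strongest summit. Of the genes named, nrde-2, hrde-1, mei-2, coh-4 and htz-1 were not. Without replicate 1 the meiosis list did not pass (odds ratio 2.45, Fisher's exact test, adjusted p = 0.131) and the odds ratio of chromatin regulators was 7.28. With the window of 500 and 100 bp that of P granule genes was 2.50.

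Among lists of broadly used genes, chaperones (cct-8, dnj-28, hsp-60 and cct-5, signal values 221, 219, 208 and 181) and respiratory chain genes (cox-5B, cox-5A, sdhd-1 and atp-1, 234, 176, 150 and 139) each had 12 of 43 members bound (odds ratio 4.91, Fisher's exact test, adjusted p = 0.000169 for each). With each summit given only to its nearest gene start, the chaperone list did not pass (odds ratio 2.30, Fisher's exact test, adjusted p = 0.192). Only 4 of the 12 bound chaperone genes were the nearest gene start to their strongest summit, and cct-8, hsp-60 and cct-5 were not. The count was 7 of 12 for the respiratory chain. Splicing factors (9 of 46, odds ratio 3.07, Fisher's exact test, adjusted p = 0.0148) were led by prp-19 (273), rsp-6 (134), and rsp-1 and rsp-2, which shared 1 summit (114). Proteasome genes (6 of 31, odds ratio 3.02, Fisher's exact test, adjusted p = 0.0479) were led by rpn-9 (141), rpn-11 (111), pas-6 (104.9) and rpn-3 (102). The splicing and proteasome lists did not pass with either library's own list (odds ratios 2.14 and 2.74 without replicate 1, 1.71 and 2.04 without replicate 2), with the other deposited list (2.56 and 2.49) or in the upper part of the list by signal value (2.47 and 2.99). Nor did splicing factors with nearest gene starts (2.74, Fisher's exact test, adjusted p = 0.0966). Bound splicing and proteasome genes were the nearest gene start in 5 of 9 and 5 of 6 cases, which leaves out prp-19, rsp-2 and rpn-3.

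Neuropeptide genes (0 of 65, odds ratio 0, upper 95% bound 0.728) and nuclear hormone receptor genes (3 of 125, odds ratio 0.305) were bound less often (Fisher's exact test, adjusted p = 0.0328 and 0.0479). Neither passed with either library's own list, where the odds ratio stayed 0 for neuropeptides and was 0.167 and 0.153 for receptors without replicates 1 and 2, or in the upper part of the list by signal value (0 and 0.324). Receptors also did not pass with the other deposited list (0.318), nor neuropeptides with the window of 500 and 100 bp or nearest gene starts (0 in both). The 3 bound receptor genes were nhr-255 (signal value 102), nhr-86 (99.5) and nhr-47 (86.5), none of them the nearest start to its summit. The other 11 lists did not pass under the main settings. Translation factors passed without replicate 1 (odds ratio 3.21, Fisher's exact test, adjusted p = 0.0187) and against all annotated genes (2.76, 0.0334), and the mitochondrial ribosome with the window of 2000 and 500 bp (2.54, Fisher's exact test, adjusted p = 0.0211). Bound members numbered 5 of 41 for histones (his-68 and his-67 sharing 1 summit, 171, his-58, 93.0, and his-46, 72.6), 7 of 50 for translation factors and aminoacyl-tRNA synthetases (eif-2Bgamma, 164, eif-3.C, 128, ears-2, 111, and eef-2, 103) and 3 of 17 for RNA polymerase subunits (rpb-12, 139, rpb-11, 87.1, and rpoa-2, 84.6). They numbered 6 of 57 for the mitochondrial ribosome (mrpl-15, 133, mrpl-12, 101, mrps-17, 84.9, and mrpl-49, 76.8), 1 of 46 for sperm proteins (spe-39, 123), 2 of 65 for homeobox genes (ceh-43, 101, and ceh-92, 72.1), 2 of 93 for cuticle collagens (col-63, 102, and col-38, 77.6) and 2 of 33 for muscle (act-2, 129, and cpn-3, 87.2). No member was bound of 32 neuronal, 22 intestinal and 5 dosage compensation genes.

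**Figure D4:**
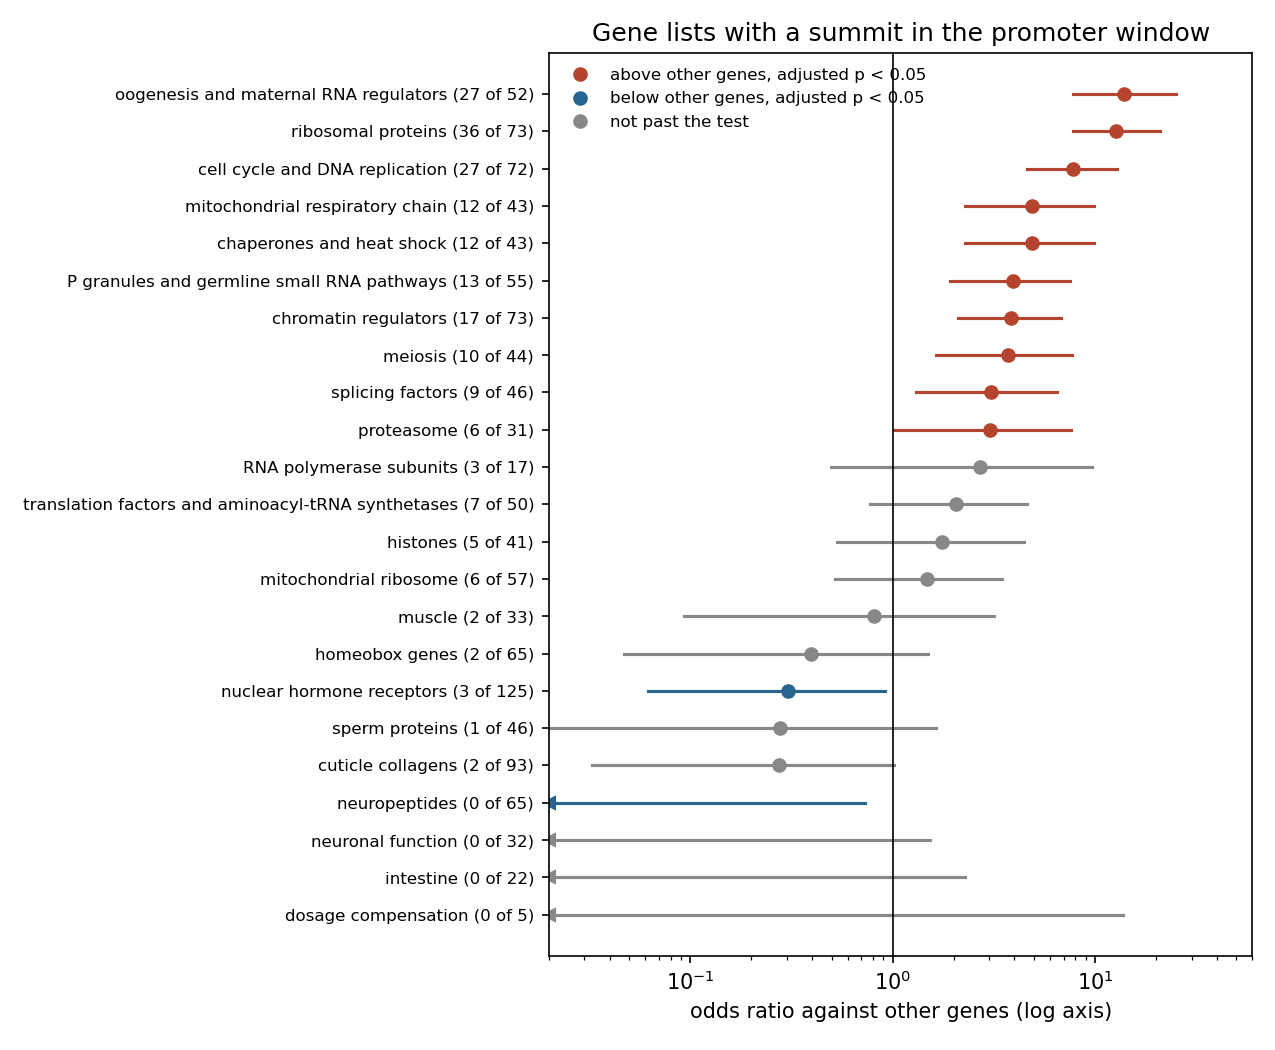
Odds ratio (x axis, log scale) of a main summit in the promoter window for each of 23 gene lists (y axis, with bound and tested members) against other protein-coding genes with a candidate. Lines are 95% intervals, arrowheads mark an odds ratio of 0, and colours mark the 10 lists above, the 2 below and the 11 that did not pass.

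Sequence at the summits was richer in G and C than the flanks. GC content was 46.6% within 50 bp of the summit and 36.1% in windows of the same width 300 bp to either side. Of 20 motifs fixed before the data were examined, 5 were more frequent at summits than in the flanks of the same peaks. The E2F-like motif TTSSCGC was in 19.7% of summit windows and 3.33% of flanks, and the EOR-1-like motif GAGACGCAG in 3.56% and 0.167%. The GC box GGGCGG (5.33% against 1.78%), the heat shock element (4.0% against 1.89%) and CTCCGCC (2.67% against 0.722%) also passed. Adjusted p (exact sign test, two-sided) was 7.03e-27, 4.63e-07, 0.000309, 0.00219 and 0.00318 in this order. The motif TTTCAG was named a trans-splice acceptor in the fixed list, but splicing was not tested. TTTCAG (7.78% against 22.9%), the GATA site TGATAA (3.22% against 8.67%), TATAAA (5.33% against 9.50%) and runs of 8 T (5.11% against 9.56%) were less frequent at summits. Their adjusted p (exact sign test, two-sided) was 8.92e-18, 9.27e-06, 0.00219 and 0.00155. Candidate summits were also matched to the peaks on annotation class, but not on GC content. Against these matched summits, the background share was 0.911% for the EOR-1-like motif, 2.73% for the GC box and 0.489% for the heat shock element. All 3 passed. No motif or 6-mer was compared at equal GC content, so composition may contribute to such differences, and how much was not measured. Higher GC content alone would not be expected to raise the heat shock element, since most of its fixed bases are A or T. Within 100 bp of the summit, the EOR-1-like motif was in 4.89% against 0.722% of flanks and TTTCAG in 22.1% against 40.8%, and in the upper part of the list the EOR-1-like motif was in 4.89% against 0.111%. TATAAA did not pass without replicate 1 (4.64% against 8.27%), without replicate 2 (4.96% against 8.21%), with the other deposited list (6.0% against 9.06%) or in the upper part of the list (4.67% against 8.67%). Its adjusted p (exact sign test) was 0.0750, 0.103, 0.0516 and 0.0556 in this order. CTCCGCC did not pass without replicate 1 (1.61% against 0.504%), in the upper part (2.00% against 0.556%) or against matched summits (2.67% against 1.69%), with adjusted p (exact tests) of 0.412, 0.292 and 0.0948. Nor did the heat shock element without replicate 1 (3.83% against 1.92%, exact sign test, adjusted p = 0.0781) or runs of 8 T within 100 bp of the summit (14.2% against 17.9%, exact sign test, adjusted p = 0.0659). The TCF site was less frequent without replicate 1 (2.42% against 6.25% of flanks, exact sign test, adjusted p = 0.0144) and against matched summits, as were ETS and the piRNA promoter core against matched summits.

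Of all 2080 6-mers merged with their reverse complements, 337 were more frequent and 280 less frequent at summits than in flanks. The 6-mers with the smallest p were CGCGCC, ACGCGC and GCGCAC. CGCGCC was in 17.1% of summit windows and 1.33% of flanks, ACGCGC in 15.8% and 1.28%, and GCGCAC in 14.1% and 1.00%. Their adjusted p (exact sign test, two-sided) was 1.97e-30, 1.83e-27 and 6.38e-27. Overlapping 6-mers, such as ACGCGC and CGCGCC, are not independent.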

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

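The test of repeated sequence was written before its result was seen. In the ranked list behind the main list, 88 regions reached the IDR threshold and were absent from the thresholded list, a signal in data that the comparisons of the report did not use as peaks. The strongest, on chromosome X at 15810953 to 15811141, had a signal value of 2023, above every peak that was kept. The median signal value was 116 in these regions and 95.7 in the kept peaks. They lay in intergenic sequence in 70 cases, in promoter windows in 15 and in coding exons in 3. In 85 of the 88 (96.6%, exact 95% interval 90.4 to 99.3), most 25-mers of the region occurred more than once in the genome, against 90 of the 900 kept peaks (10%). Repeated sequence may therefore account for most of these regions. Which step left them out is not given in the sources used here, and no biological explanation was tested, since the samples form a single group.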

How the results depend on the processing

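The alternatives without weaker overlapped peaks, with promoter summits only, without tRNA gene summits, for single autosomes, and with nearest gene starts for gene classes and divergent genes were chosen after seeing the data, and the others before the data were examined. Across 80 alternative values of the results that answer a comparison, 73 kept their direction and their side of the threshold, or stayed within 1.5 times a count or within the 95% interval of a share. The promoter odds ratio ranged from 5.24 to 11.9 and the X chromosome odds ratio from 0.132 to 0.339, all past the threshold. The number of gene lists past the threshold ranged from 8 to 13 against 12, and it was 8 with either library's own list, which has fewer peaks.

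The share of replicate 1 peaks found in replicate 2, and the reverse, moved to 72.9% and 77.0% in the upper part of each list by signal value (262 and 248 peaks), and to 96.8% and 96.8% when all candidates of the other library were searched, a longer list by construction. With the other deposited list, 56.8% and 53.7% of peaks were in the lists of replicates 1 and 2. Without replicate 1 or 2, 380 to 413 6-mers passed against 617, with fewer peaks tested.

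Of 480 alternative values for single autosomes, gene classes, gene lists and motifs, 421 were the same, 32 no longer passed, 8 newly passed and 19 changed direction. Those that changed direction had not passed under the main settings or under the alternative, and the cause was not tested. For miRNA genes the odds ratio was 0.559 in the upper part of the list, 0.662 with the window of 500 and 100 bp and 0.181 with nearest gene starts. For the mitochondrial ribosome it was 0.760 with the other list, 0.730 in the upper part and 0.354 without replicate 1, but 1.06 without replicate 2, with no change of direction. It was 0.753 for histones with the window of 500 and 100 bp, and 1.00 for muscle against all genes. The share of summits with the BLMP-1-like motif was 0.577% in the other list, 0.444% in the upper part, 1.00% within 100 bp and 0.382% without replicate 2, but tied with the flanks without replicate 1 (0.605%). The PHA-4-like motif was in 28.2% in the upper part and 46.3% within 100 bp, and MYB in 25% within 100 bp. CRE was in 0.444% in the upper part and 0.403% without replicate 1, and AP-1 in 0.444% and 0.403%. Without replicate 2 neither changed direction (0.191% and 0.954%). Depth is unknown, so its effect on weak peaks could not be measured.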

Other observations

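The tests in this part were written before their results were seen, except that of muscle and intestine genes, the chi-square test without GC classes, the tRNA comparison with all summits, the motif counts by gene list, the 8-mers and the count of overlapped weak peaks, which were chosen after. The E2F-like motif was counted at the peaks of the 10 lists with more peaks than other genes, each against other promoter peaks, and 1 list passed. Of 28 peaks in windows of cell cycle and DNA replication genes, 16 (57.1%) had the motif within 50 bp of the summit, against 20.6% of 698 other promoter peaks (odds ratio 5.11, 95% interval 2.21 to 12.1, Fisher's exact test, adjusted p = 0.000401 over 10 lists). The other 9 did not pass (Fisher's exact test, adjusted p of 0.0610 to 1). Their counts were 2 of 35 for ribosomal proteins, 12 of 31 for oogenesis and maternal RNA regulators, 7 of 17 for chromatin regulators, 5 of 13 for P granule genes, 4 of 8 for splicing factors, 4 of 12 for chaperones, 2 of 9 for meiosis, 2 of 6 for the proteasome and 0 of 12 for the respiratory chain. The lists were not tested against each other. The 8-mers with the smallest p at summits were AAAGGCGC (6.56% against 0.444% of flanks), GCGAGACC (6.22% against 0.333%) and AAGGCGCA (5.44% against 0.278%), with adjusted p of 1.08e-09, 1.96e-09 and 2.49e-08 (exact sign test). AAAGGCGC and AAGGCGCA overlap and are not independent.

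On the X chromosome 35 of 55 peaks (63.6%) had their summit in a tRNA gene window, against 58 of 845 (6.86%) on the autosomes. By chromosome, a main summit was in the window of 47 of 233 tested tRNA genes on X (20.2%), 20 of 60 on IV (33.3%), 14 of 51 on I (27.5%), 14 of 53 on II (26.4%), 12 of 59 on III (20.3%) and 8 of 67 on V (11.9%).

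The excess of peaks at tRNA genes was set against 3 technical explanations. Reads shared evenly between identical copies would give summits at all copies or none, but 39 of 40 groups of identical tRNA genes with a summit (97.5%, exact 95% interval 86.8 to 99.9) also held copies without one. This cannot exclude shared reads, because a summit counted anywhere in the promoter window, most of which lies outside the copy. The absence of repeated regions from the thresholded list could also leave copies without a summit. Peaks of neighbouring protein-coding promoters did not account for all of it. Without such summits 87 of 444 tRNA genes (19.6%) and 3.26% of other genes, none of them protein-coding, held a peak, an odds ratio of 7.22 (95% interval 5.46 to 9.48). With all summits the shares were 22% and 4.52% of other genes that are not protein-coding (odds ratio 5.95, 4.69 to 7.52), so the higher ratio without them reflects a lower share in the comparison genes, not more bound tRNA genes. Repeated sequence at the summit stayed open: the median tRNA peak had 57.1% of its 25-mers found once in the genome (bootstrap 95% interval 46.7 to 70.1), between the bounds set beforehand, and 100% in all main peaks. No biological explanation was tested.

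GC content at the candidate summit may contribute to the lists with more peaks than other genes, since 3.38% of protein-coding genes were bound in the lowest of 5 equal classes of summit GC content and 11.4% in the highest, but 9 of the 10 lists stayed past the threshold when genes were compared within classes. The exception was the proteasome list, whose odds ratio was 3.02 (1.24 to 7.39) without classes and 2.98 (1.22 to 7.29) within them. It missed the threshold in both cases in this Cochran-Mantel-Haenszel chi-square test (adjusted p = 0.0631 and 0.0635), so its call ended with the change from Fisher's exact test, not with the classes. The same held for both lists with fewer peaks, neuropeptides (chi-square test, adjusted p = 0.0850 without classes and 0.0635 within, odds ratio 0 in both) and nuclear hormone receptors (0.0926 and 0.0902, odds ratios 0.305 and 0.302). Abundant transcription in any tissue stayed open. Of 55 muscle and intestine genes 2 were bound, and the upper 95% bound of their odds ratio, 1.79, exceeded the lower bounds of the proteasome, splicing and meiosis lists (1.01, 1.30 and 1.63) and lay under those of the other 7 lists (1.92 to 7.77). The lower bounds were chosen for this comparison after the value was seen, in place of the lowest odds ratio of the 10 lists, 3.02, which lay above it. Transcript levels were not measured here, so these lists do not settle it for any of the 10. Whether the same promoters hold peaks of any tagged protein stayed open, because control libraries and other proteins were not analysed here, and no biological explanation was tested.

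Of 20 main peaks with a signal value under 40, 18 (90%) overlapped a stronger peak that also passed the threshold, against 1 of the other 880.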
